A study of Mus musculus with 5 samples.

How the data were processed

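The deposited table holds log2 expression values of 45037 probe sets and 64 manufacturer's controls on 5 Affymetrix mouse arrays, 3 of CDP and 2 of CMP. Per the labels' protocols, CDP or CMP were sorted and then sorted again, total RNA was extracted with Trizol and linear acrylamide, and the RNA was amplified over 2 cycles and labelled with biotin. Per the submitters' processing notes the authors used GCRMA, which corrects background by probe sequence, normalizes quantiles between arrays and summarises the probes of a set. No version is given in the sources used here, nor is it stated whether all arrays were processed together. The deposited log2 values run from a shared lowest value of 2.256 to 16.59, and 32.1% to 36.5% of probe sets lay within 0.005 of that lowest value on each array. Such values have no order among themselves. The number of arrays limits the precision.

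Groups and replicate numbers were taken from the sample titles. The title of CDP 3 begins with CM where the others begin with BM, without a stated reason, and its other labels give the tissue as marrow and the cells as CDP. Replicates 1 and 2 occur in both groups, but no label says that a number marks a shared animal or day, so replicates were not paired. No 2 arrays were duplicates, since the closest pair (CDP 2 and CDP 3) correlated at 0.974 across tested probe sets. Arrays were not always closest within their group. CMP 1 and CMP 2 correlated at 0.895, less than CMP 1 with CDP 1 (0.924) or CMP 2 with CDP 2 (0.911) and CDP 3 (0.900). No column of the table was left unmapped.

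Probe sets were named through the platform annotation given with the table. Of 45037 probe sets without the controls, 34945 had 1 gene symbol, 932 had several and 9160 had none, and only those with 1 symbol were named. Symbols were checked by gene identifier against the RefSeq table of GRCm38.p6, used for names only, and 0 changed. No genome build is given in the sources used here, so no positions are printed. Some genes of the lists had no probe set named here and are not reported.

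Probe sets were tested when at least 2 of the 5 arrays reached log2 5, where 2 is the size of the smaller group, which left 16552 probe sets, 14225 of them with 1 symbol, covering 8449 genes. The deposited values were not normalized again. CDP was compared with CMP in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, 2-sided, with 3 residual and 3.14 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all tested probe sets. All adjusted p-values of genes are from this fit unless a setting is named, and the threshold was 0.05. Differences are CDP minus CMP in log2 units with the standard error of the fit, and group values are mean ± SD with n = 3 for CDP and n = 2 for CMP. For a gene with several tested probe sets the one with the highest mean was used. Of the 16 named genes with several, probe sets disagreed in sign for 1, Uty. Of 13 called ones, 9 had another probe set that did not pass (Ccr2, Gata2, Irf8, Kif23, Lair1, Socs3, Tfr2, Tifab and Tyms). The probe sets of 14 named genes are marked as able to match several transcripts (Ptpro, S100a6, Ctla2a, Tfr2, Myct1, Hdc, Ak4, Kit, Fcgr2b, Id2, Gata2, Mx1, Ier3 and Socs3). Log2 5 also served as the detection level. Where any array of the dimmer group lay below it, the fold is a lower bound, computed with values below 5 set to 5. Standard errors and p-values use the deposited values instead. Where a whole group lay below the level, its SD is that of undetected values, such as 0 for Fn1 and Itgax in CMP.

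The gene lists, the rule for the genes named and the settings to compare were fixed before the data were examined, except where stated. The rule took the 12 genes with the largest called difference in each direction and no overlap between groups, all genes of the sorting gate, up to 4 called genes of each list by smallest p, Irf8, Cebpa, Gfi1, Spi1, Gata1 and Gata2 whatever their values, and Y-linked genes and control probe sets as checks. Of 25 lists, 21 had at least 3 tested genes and were tested with camera in limma at a preset correlation of 0.01, adjusted over the 21. Genes that failed the filter are left out of the counts and medians of their lists. The lists of the gate and the sex chromosomes were only described, and those of T and NK cells and of the stroma had 2 tested genes each. Alternatives were quantile or median scaling, 3 other filters, trended or robust variance, array weights, the replicate number as a block, removal of probe sets that may cross-hybridize, the mean of a gene's probe sets, fry and an estimated correlation for the lists, and leaving out each array. Chosen after seeing the data were the arrays low in 5′ beta-actin signal (below log2 8) as a block or left out, 3′ minus 5′ control differences as covariates, centring on tested probe sets, lists without gate genes, and a filter on the mean of either group.

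The procedure was tested on simulated data for this comparison, with 16552 probe sets at their real means, variances drawn from the fitted prior, and 200 probe sets changed. Of 50 changed by log2 1, 0 were recovered, of 50 at log2 2 also 0, of 50 at log2 4 there were 35, and of 50 at log2 6 there were 45. Among 84 calls 4 were of unchanged probe sets. Only bright probe sets were changed, no lowest value was imposed, and no simulated array was low in 5′ signal. These counts therefore do not describe calls where a whole group lay below detection. A list shifted by log2 1 was called and no other list was. The simulated probe sets varied independently of each other, so this cannot show how list calls behave where genes vary together. In the real data the estimated correlation within the same list, of ribosome biogenesis and Myc targets, was 0.43.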

Results

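Gene expression was measured in 2 progenitor populations that had been sorted from marrow of C57BL/6 mice of wild-type genotype, on 5 Affymetrix mouse whole-genome arrays. The common dendritic cell progenitor (CDP, 3 arrays) gives rise to dendritic cells, and the common myeloid progenitor (CMP, 2 arrays) lies upstream of granulocytes, monocytes, erythroid cells and megakaryocytes. Per the series' design text, both were lineage-negative, CD34-positive and Flk2-positive, without CD16 and CD32. CDP had intermediate c-Kit and carried CD115, whereas CMP had high c-Kit and lacked CD115 and CD11c. RNA came from 10000 to 30000 cells and passed through 2 rounds of amplification. The series' title places the comparison in a study of IRF-8, dendritic cell commitment and neutrophil production, so the question addressed here is which genes differ between the progenitor already committed to dendritic cells and the earlier myeloid progenitor. The labels do not say whether arrays came from separate animals, so p-values measure the spread between these samples, which may be technical. For genes with a group wholly below detection, p-values rest in part on the spread of undetected values.

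The share of probe sets at or above log2 5 was alike on all arrays, from 34.0% on CMP 1 to 35.8% on CDP 2. The 3′ to 5′ balance of the control probe sets was not. The 3′ and 5′ beta-actin control probe sets differed by 8.05 (log2) on CDP 1 and 7.35 on CMP 1, against 2.12 on CDP 2, 4.48 on CDP 3 and 1.81 on CMP 2. CDP 1 and CMP 1 are therefore called the arrays low in 5′ signal, and differences within the 2 kinds of array are given below. The Gapdh pair split the arrays otherwise, with the widest gap on CDP 3 (6.60) and 4.64, 3.88, 4.71 and 3.22 on CDP 1, CDP 2, CMP 1 and CMP 2. The Y-linked genes Kdm5d, Eif2s3y and Uty were detected on all 5 arrays, with CDP minus CMP at 0.06 ± 0.31 (SE), 0.18 ± 0.40 and 0.07 ± 0.33, none past the threshold. Xist, expressed from the inactive X of female cells, was seen on CDP 2 alone (7.75, and 5.48 on a second probe set).

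The genes of the sorting markers differed as follows. Itgax, which encodes CD11c, was at 7.22 ± 0.74 (log2, mean ± SD, n = 3) in CDP and close to the table's lowest value on both CMP arrays, at least 4.67-fold higher in CDP (limma, adjusted p = 0.0155). Kit was lower in CDP, at 7.54 ± 0.31 against 10.12 ± 0.11, a difference of -2.57 ± 0.34 (SE, adjusted p = 0.0318). Csf1r, which encodes CD115, was at 13.02 ± 0.12 in CDP and 11.39 ± 0.51 in CMP, a difference of 1.63 ± 0.35 that missed the threshold (adjusted p = 0.0966), while a second of its 3 probe sets passed it at 2.13 ± 0.29 (adjusted p = 0.0355). Csf1r transcript was thus abundant in CMP, which had been sorted without the surface protein. Flt3, which encodes Flk2 (0.92 ± 0.30), Cd34 (-1.33 ± 0.56), Fcgr2b (0.76 ± 0.42) and Fcgr3 (-0.21 ± 0.40) did not pass. Adjusted over the list alone, 3 of these 7 genes were higher and 1 lower in CDP.

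Among the genes called between CDP and CMP, CDP held more Lgals3, Marchf1, Lgmn, Ctsh and Itgax transcript, with the transcription factors Irf8, Id2, Mycl, Id3 and Irf5. CMP held more Ctla2a, Tfr2, Cpa3, Hdc, Angpt1 and Gata2. Of 16552 probe sets tested with limma, 217 were higher and 70 lower in CDP at an adjusted p under 0.05, together 287, and at 1 probe set per gene these came to 141 genes higher and 40 lower. On all 287 probe sets every CDP array lay on one side of every CMP array. That holds for 32.2% of all tested probe sets, where chance alone gives 20% for 3 arrays against 2. The median difference over all tested probe sets was 0.12, and quantile normalization moved it to 9.12e-05. Medians of gene lists are therefore given relative to 0.12, and the smallest difference called was 1.86.

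**Figure D1:**
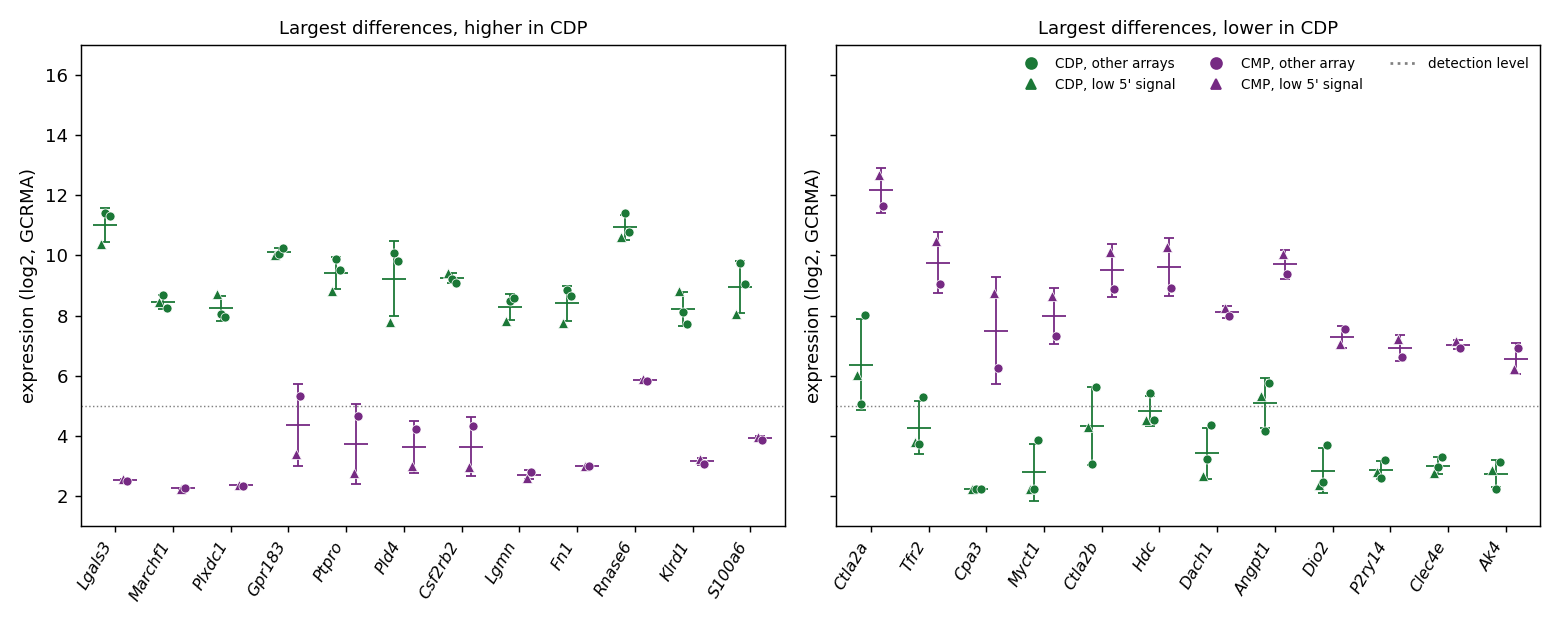
Expression (log2, GCRMA) on each array of the 12 genes with the largest called log2 difference in each direction, values below detection included, with CDP in green and CMP in purple, triangles for the arrays low in 5′ signal, and horizontal bars with whiskers for the group mean ± SD (n = 3 and n = 2). The dotted line is the detection level of log2 5, and CDP and CMP arrays do not overlap for any of the 24 genes.

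Among the 12 genes with the largest called log2 rise in CDP, Lgals3, which encodes galectin-3, went from 2.54 ± 0.05 in CMP to 11.03 ± 0.56, at least 65.2-fold (adjusted p = 0.00719). Where arrays of the dimmer group lay below log2 5, only such a lower bound can be given, with values below 5 set to 5, and the order among bounded genes carries no meaning. Who is among the 12 rests on log2 differences that include values below detection, so genes outside may differ by more, such as Ctsh at 31.5-fold. Marchf1, a ubiquitin ligase that turns over surface MHC class II, rose at least 10.9-fold, and Lgmn, a lysosomal protease, at least 9.77-fold. Csf2rb2, the IL-3 receptor beta chain found in mice, rose at least 18.9-fold. Its close copy Csf2rb was at 1.35 ± 0.41 on its brighter probe set, and neither of its 2 probe sets passed, and cross-hybridization between the copies was not excluded. Pld4, an endolysosomal nuclease, rose at least 18.7-fold (30.6-fold without CDP 1) and Klrd1, which encodes the lectin-like receptor CD94, at least 9.34-fold. Gpr183, an oxysterol receptor that guides migration, rose at least 30.6-fold (adjusted p = 0.0164) and Rnase6 33.8-fold (5.08 ± 0.36 SE, adjusted p = 0.00828). The other genes of the 12 were Ptpro, Fn1, S100a6 and Plxdc1, with bounds of 21.2-fold, 10.6-fold, 15.4-fold and 9.47-fold.

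Among the 12 genes with the largest called log2 fall in CDP, chosen in the same way, Ctla2a was at -5.78 ± 0.88 (55.1-fold lower, adjusted p = 0.0432) and its near-copy Ctla2b was at least 19.6-fold lower. The probe set of Ctla2a is marked as able to match several transcripts, so the 2 genes may not be measured apart. Tfr2, a transferrin receptor, was at least 25.3-fold lower on its brighter probe set, which carries the same mark, and did not pass on another (adjusted p = 0.0566). Hdc, the enzyme that makes histamine, was at least 22.1-fold lower. Cpa3, a mast cell protease, was at the table's lowest value on all 3 CDP arrays and at 7.51 ± 1.77 in CMP, at least 5.68-fold lower in CDP. Angpt1, the ligand of Tie2, was at least 20.2-fold lower. Myct1 was at least 8.0005-fold lower. Dach1, Dio2, P2ry14, Clec4e and Ak4 were lower in CDP by at least 8.68-fold, 4.90-fold, 3.80-fold, 4.11-fold and 2.98-fold. Nkg7 and Ier3, outside the 12, had larger folds or bounds than these 5. Leaving out 1 array moved some folds by over 1.5 times. That of Ctla2a became 35.0-fold without CDP 2 and 97.4-fold without CDP 3. Without CMP 1 and without CMP 2 the bounds became 15.4-fold and 41.6-fold for Tfr2, 2.38-fold and 13.5-fold for Cpa3, 5.06-fold and 12.6-fold for Myct1, 12.8-fold and 30.1-fold for Ctla2b, and 13.8-fold and 35.4-fold for Hdc.

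Irf8, the factor named in the series' title, was detected in both populations, at 15.17 ± 0.10 in CDP and 12.56 ± 0.48 in CMP. It was 6.12-fold higher in CDP (2.61 ± 0.34 SE, adjusted p = 0.0318), and a second probe set gave 2.78 ± 0.53 without passing (adjusted p = 0.0694). Id2, an inhibitor of E proteins needed by some dendritic cells, was 17.9-fold higher, Irf5 5.13-fold, Mycl at least 8.21-fold and Id3 at least 2.78-fold. Gata2, a factor of stem, mast and megakaryocytic cells, was 6.83-fold lower (-2.77 ± 0.38, adjusted p = 0.0349). Gfi1 and Cebpa, both needed for neutrophil formation, were at -3.20 ± 0.59 (adjusted p = 0.0628) and -1.86 ± 0.47 (adjusted p = 0.136) and did not pass. Spi1, which encodes PU.1, was at 0.41 ± 0.63 (adjusted p = 0.818), and Gata1 stayed below log2 3.74 on every array. Of 22 tested myeloid lineage factors, 4 rose, 1 fell and 17 did not pass. Adjusted over the list alone, 5 were higher and 4 lower. The list as a whole did not pass (camera adjusted p = 0.396), with a median of -0.18 relative to 0.12. Its unshifted median (-0.07) and unshifted mean (0.23) had opposite signs. Of 15 dendritic cell factors 3 rose, none fell and 12 did not pass, with 7 higher adjusted over the list alone. As a group they were higher in CDP (relative median 0.90, camera adjusted p = 0.00011, and adjusted p = 0.178 with an estimated correlation).

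**Figure D2:**
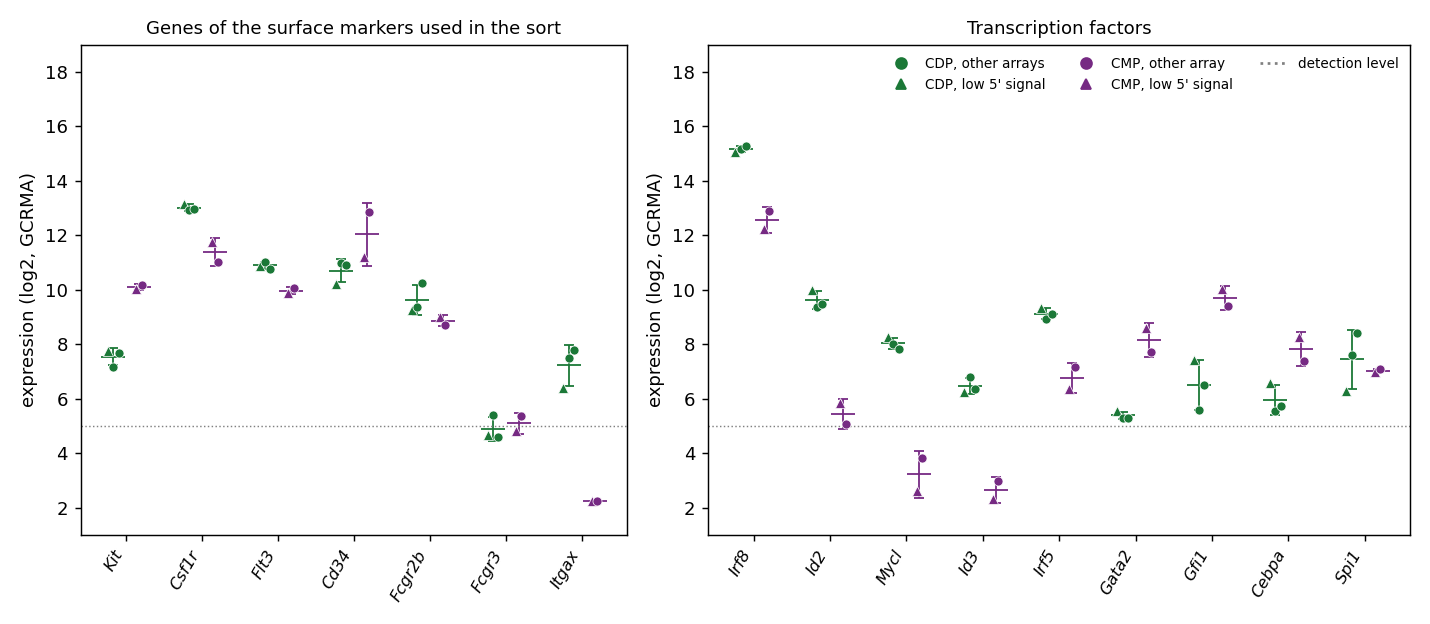
Expression (log2, GCRMA) on each array of 7 genes of the sorting markers (left) and 9 transcription factors (right), with CDP in green, CMP in purple, triangles for the arrays low in 5′ signal, bars and whiskers for the group mean ± SD (n = 3 and n = 2) and a dotted line at the detection level of log2 5. Irf8 lies at 15.17 in CDP and 12.56 in CMP on average, and Itgax lies far below the dotted line on both CMP arrays.

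Some genes of dendritic cells and monocytes were higher in CDP, while markers such as Xcr1, Ccr7, Cd209a, Siglech, Itgam and Mrc1 stayed below log2 5 on every array. Of 24 conventional dendritic cell markers with a probe set, 12 were tested. Of these 4 rose, namely Itgax, Plbd1 (at least 6.55-fold), the lectin Clec10a (at least 12.8-fold) and Naaa (at least 1.92-fold), and 8 did not pass, with 9 higher adjusted over the list alone. Their relative median was 1.36 (camera adjusted p = 1.53e-06, and adjusted p = 0.182 with an estimated correlation). Since 2 of these 12 belong to the sorting gate, the test was repeated without gate genes, and the list still passed (adjusted p = 3.13e-05). Of 22 plasmacytoid dendritic cell markers with a probe set, 12 were tested. Siglech, Tlr7, Tlr9, Irf7, Ccr9, Ly6d and Pacsin1 were not, as they stayed below log2 5 on every array. Of the 12 tested, Pld4 and the inhibitory receptor Lair1 (at least 4.71-fold) rose and 10 did not pass, with 7 higher and 1 lower adjusted over the list alone. Their relative median was 2.13 (camera adjusted p = 0.000494, and adjusted p = 0.178 with an estimated correlation). Of 18 monocyte and macrophage genes 6 rose and 12 did not pass, with 13 higher adjusted over the list alone. S100a4 rose at least 16.99-fold, Tifab 6.36-fold on its brighter probe set (1.53 ± 1.21 on another, adjusted p = 0.615), Irf5 5.13-fold and the chemokine receptor Ccr2 3.998-fold. All 18 differences were positive, with a relative median of 1.58 (camera adjusted p = 6.13e-09, and adjusted p = 0.125 with an estimated correlation).

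In the MHC class II and antigen presentation list, Lgmn and the protease Ctss (4.30-fold) rose and the other 9 of 11 did not pass, with 4 higher adjusted over the list alone. Both are proteases rather than class II chains. Of 2 chains picked after their values were seen, H2-Aa was at least 6.79-fold higher without passing (adjusted p = 0.0818) and H2-Ab1 did not pass (adjusted p = 0.916). H2-Aa passed over the list alone (adjusted p = 0.00683) and with the arrays low in 5′ signal as a block (adjusted p = 0.0295). The probe sets of both chains are marked as able to match several transcripts. Of 19 genes of the list with a probe set, 11 were tested, and Cd74, H2-Eb1 and Ciita stayed below log2 5 on every array. The list's relative median was 1.66 (camera adjusted p = 0.00142, and adjusted p = 0.230 with an estimated correlation). Of 29 lysosome and phagocytosis genes 4 rose and 25 did not pass, with 8 higher adjusted over the list alone. These 4 were Lgmn, Ctss, the protease Ctsh (31.5-fold, or 19.5-fold without CMP 1 and 50.7-fold without CMP 2) and the adaptor Tyrobp (3.92-fold). Their list's relative median was 0.79 (camera adjusted p = 5.87e-06, and adjusted p = 0.230 with an estimated correlation). In both lists the medians were above 0 between arrays low in 5′ signal and between the others, at 1.04 and 1.65 for the first and 0.96 and 0.73 for the second. The first list's unshifted median went from 1.77 to 1.12 without CMP 1, and the second's from 0.91 to 1.60 without CMP 2.

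Receptor genes moved both ways. Of 13 pattern recognition genes, Tlr1 (at least 3.81-fold) and the beta-glucan receptor Clec7a (5.16-fold) rose, Clec4e, a receptor for mycobacterial glycolipid, fell, and 10 did not pass, with 5 higher and 2 lower adjusted over the list alone. The relative median was 1.04 (camera adjusted p = 0.0446, and adjusted p = 0.390 with an estimated correlation), and the call held in 17 of 25 settings. Leaving out CDP 2 or CDP 3 ended it at adjusted p = 0.0993 and 0.0781, as did fry (0.063), median scaling (0.0563), the filter at log2 4 (0.0682), gene means (0.0638) and the Gapdh covariate (0.0507). Without CMP 2 the unshifted median went from 1.16 to 1.84. Of 14 chemokine receptor and adhesion genes, Ccr2 and Cx3cr1 (6.63-fold) rose and 12 did not pass, with 7 higher and 1 lower adjusted over the list alone. The relative median was 0.77 (camera adjusted p = 0.0312, and adjusted p = 0.196 with an estimated correlation), and the call ended without CDP 1 (adjusted p = 0.0808) or CMP 1 (adjusted p = 0.1465), and without both arrays low in 5′ signal (adjusted p = 0.181). Without CMP 2 the unshifted median went from 0.89 to 1.43. Of 23 growth factor and cytokine receptors, Csf2rb2, Il7r (at least 2.27-fold) and Il13ra1 (at least 1.34-fold) rose, Kit fell and 19 did not pass, with 7 higher and 2 lower adjusted over the list alone. That list did not pass (camera adjusted p = 0.113).

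Some genes of stem cells, mast cells, neutrophils and megakaryocytes were lower in CDP. Of 22 stem cell and multipotent progenitor genes 5 fell, none rose and 17 did not pass, with 12 lower adjusted over the list alone. Angpt1, Myct1, Kit and Gata2 led them, and the relative median was -1.41 (camera adjusted p = 1.72e-11, and adjusted p = 0.125 with an estimated correlation). Without the 2 gate genes Kit and Cd34 the list still passed (adjusted p = 7.19e-10). Of 5 tested mast cell, basophil and eosinophil genes, of 21 with a probe set, Hdc, Cpa3 and Gata2 fell and 2 did not pass. Adjusted over the list alone 4 were lower and 1 higher (relative median -2.89, camera adjusted p = 3.13e-05, and adjusted p = 0.125 with an estimated correlation). Of 10 neutrophil and granule genes 2 fell and 8 did not pass, with 3 lower adjusted over the list alone. These were Nkg7 (at least 11.1-fold lower), a granule protein also of cytotoxic lymphocytes, and Ms4a3 (6.39-fold lower), a gene of granulocyte and monocyte progenitors. The list's relative median was -0.92 (camera adjusted p = 7.52e-06, and adjusted p = 0.178 with an estimated correlation). Its unshifted median of -0.81 became -0.50 without CDP 1 or without CMP 2, and -1.42 without CMP 1. Over all settings that median came as near to 0 as -0.0012. The list leaves out 15 further genes that failed the filter, 9 of which, such as S100a8, Ngp, Camp and Ltf, were seen on CDP 2 alone, at up to 12.52, and not above 3.74 on any other array. Transcripts of mature neutrophils were thus seen on CDP 2 and not on the others. Of 7 megakaryocyte and platelet genes Pf4, or platelet factor 4, fell by at least 1.68-fold and 6 did not pass, with 1 lower adjusted over the list alone. The relative median was -0.74 (camera adjusted p = 0.00487, and adjusted p = 0.181 with an estimated correlation), and the call ended without CMP 2 (adjusted p = 0.181), with the filter at log2 7 (0.320) and with fry (0.137). The unshifted median of -0.62 nearly vanished without CMP 2 (-0.05), and was -0.94 without CDP 2 or without CMP 1. None of 7 tested erythroid genes, of 22 with a probe set, passed, alone or adjusted over the list alone, nor did their list (camera adjusted p = 0.350).

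Few lymphoid genes were called. Of 12 genes of lymphoid priming and the B lineage, Il7r, the interleukin-7 receptor, rose and 11 did not pass, with 5 higher adjusted over the list alone, and 3 of the 12 differences were negative. The relative median was 1.04 (camera adjusted p = 0.0068, and adjusted p = 0.230 with an estimated correlation), and the call ended without CMP 2 (adjusted p = 0.101) and with the filter at log2 7 (0.239). Of the T and NK cell genes, 19 stayed below log2 5 on every array and only Klrd1 and Cd28 could be tested, of which Klrd1 rose. Both were higher adjusted over the list alone. Of the stromal and endothelial genes 2 could be tested, neither passed, and 1 was higher adjusted over the list alone, while 16 stayed below log2 5 on every array.

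The lists of cell cycle and growth genes rest on shifts of many genes, few of them called. Among 29 G2 and mitosis genes 28 differences were positive. Kif23, a kinesin of cytokinesis, rose 4.50-fold, 28 genes did not pass, and 14 were higher adjusted over the list alone. The relative median was 1.02 (camera adjusted p = 5.55e-08, and adjusted p = 0.125 with an estimated correlation). Among 28 S phase and replication genes Tyms, or thymidylate synthase, rose 4.61-fold on its brighter probe set and not on another (0.34 ± 0.36), 27 did not pass and 2 were higher adjusted over the list alone, without a call for the list (camera adjusted p = 0.108). Among 29 genes of ribosome biogenesis and Myc targets 28 differences were negative, but no gene passed, alone or adjusted over the list alone. Their relative median was -0.69 (camera adjusted p = 1.53e-07, and adjusted p = 0.230 with an estimated correlation), and fry did not call the list (adjusted p = 0.253). Without CMP 1 the unshifted median went from -0.57 to -1.10. Of 28 immediate early and stress genes, Ier3 (9.77-fold lower) and the cytokine signalling inhibitor Socs3 (6.31-fold lower) fell and 26 did not pass, with 2 lower adjusted over the list alone. The relative median was -0.40 (camera adjusted p = 0.00011, and adjusted p = 0.230 with an estimated correlation), and the call ended without CMP 2 (adjusted p = 0.0522) and with fry (0.153). The unshifted median of -0.28 became -0.15 without CMP 2 and -0.85 without CMP 1. Of 20 interferon response genes Mx1 rose (at least 1.93-fold), Rtp4 fell (at least 4.21-fold lower) and 18 did not pass, with the same 1 higher and 1 lower adjusted over the list alone and no call for the list (camera adjusted p = 0.108).

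**Figure D3:**
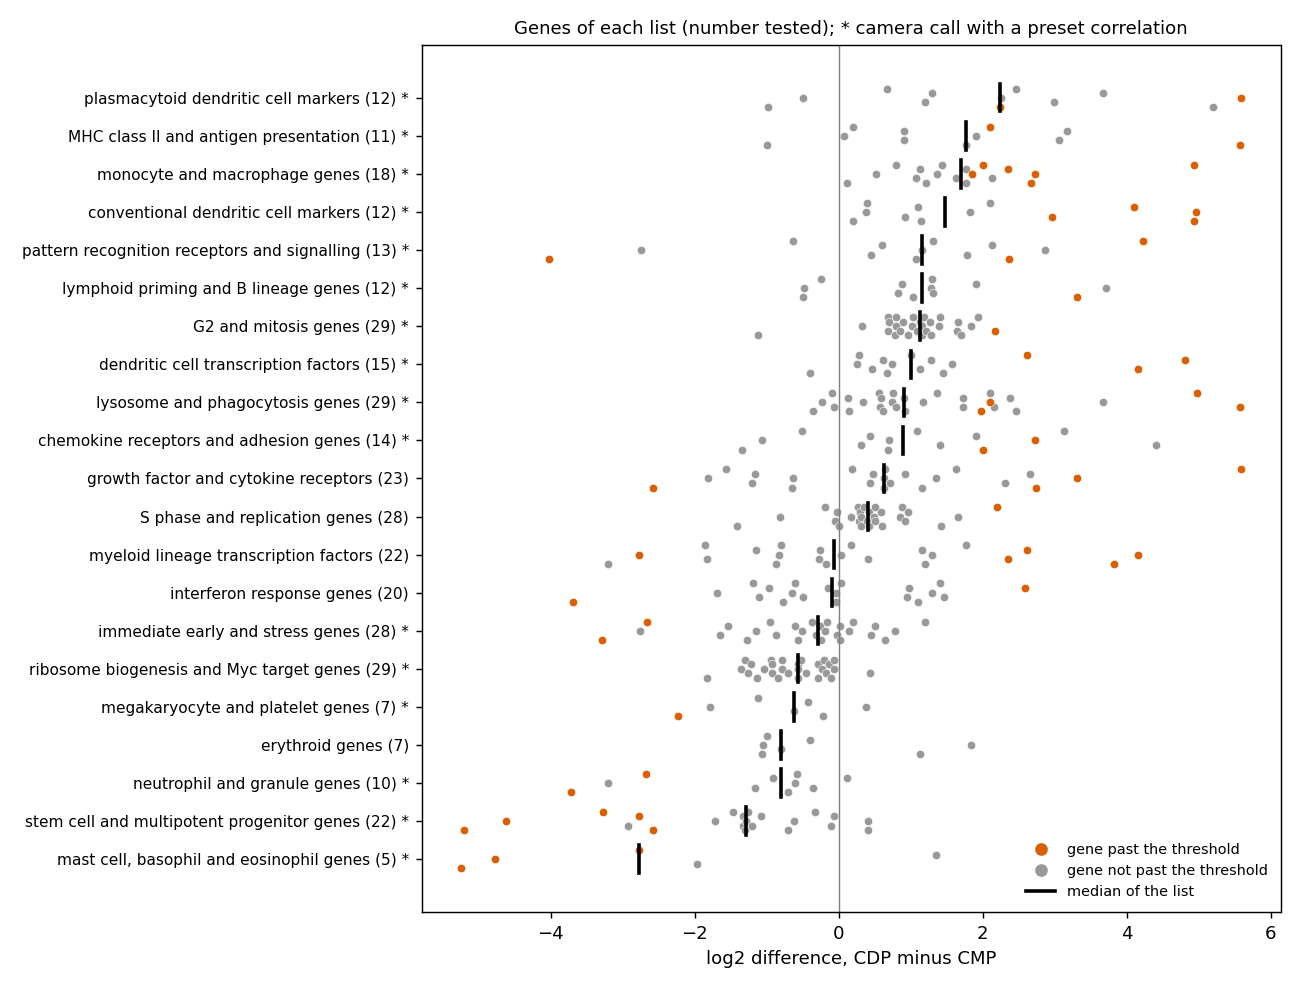
Differences in log2 expression, CDP minus CMP, of the tested genes of 21 lists, 1 point per gene, with called genes in orange, the others in grey and the list's median as a black bar. Values are not shifted by the overall median of 0.12, the number of tested genes stands in brackets, and an asterisk marks the 16 lists that passed camera with the preset correlation.

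In total 16 of 21 lists passed camera with a preset correlation of 0.01, 10 higher and 6 lower in CDP, and none passed with a correlation estimated from these arrays. Within the arrays low in 5′ signal and within the others the 10 higher lists had medians of 0.49 to 2.31 and of 0.73 to 1.92, and the 6 lower lists of -3.06 to -0.13 and of -2.40 to -0.75. Adding this split as a block kept all 16 calls (adjusted p from 4.56e-11 to 0.0243). With values below log2 5 set to 5, the medians were 0.89 to 1.82 for the higher and -2.51 to -0.28 for the lower lists. All 287 called probe sets went the same way within both kinds of array. Their groups did not overlap, so this was fixed in advance, and they were selected on the same data. Of all tested probe sets 65.0% went the same way. Across all tested probe sets, which are not independent replicates, the 2 within-kind differences correlated with r = 0.56. With the block limma called 1438 probe sets, 1024 higher and 414 lower, among them all 287. Under it Gfi1 (-3.02 ± 0.38, adjusted p = 0.00976), Cebpa (-1.70 ± 0.26, 0.0152), Csf1r (1.70 ± 0.27, 0.018) and Cd34 (-1.52 ± 0.31, 0.035) also passed. Over all settings their adjusted p ranged from 0.00434 to 0.376, 0.0106 to 0.498, 0.018 to 0.420 and 0.035 to 0.865.

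The calls of single genes rest on all arrays. Leaving out CDP 1 left 44 calls, and leaving out CDP 2, CDP 3, CMP 1 or CMP 2 left 0 with limma, where 1535, 1490, 2587 and 2766 probe sets had an unadjusted p under 0.05, against 2640 with all arrays.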

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

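The tests of the array split, of scaling and of the filter as sources of the excess of higher calls, and the split itself, were chosen only after the results were seen. No group had the 4 arrays needed for an outlier test. Control measurements, which were not tested as genes, exceeded the highest CMP array by over 1 (log2) on 3 occasions, the first of them used as a covariate in an alternative. The Gapdh 3′ minus 5′ difference was 6.60 on CDP 3 against at most 4.71 in CMP. The control probe set for dap, a bacterial transcript, was at 7.76 on CDP 1 against at most 5.63 in CMP. That for thr was at 4.52 on CDP 1, below the detection level, against at most 2.263 in CMP. In the other direction the bioB control was at 11.91 on CMP 1 against at most 10.41 in CDP.

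The replicate 1 arrays of both groups deviated alike: their deviations from the group means correlated at 0.61 across tested probe sets, which are not independent. Loss of signal away from the 3′ end predicts that 2 probe sets of 1 gene shift unequally and that this inequality repeats in the other group. Over 2183 genes it did, with r = 0.61 (95% interval 0.58 to 0.64). Any effect particular to probe sets and shared by these arrays predicts this too, and probe positions were not used. Unequal loss along transcripts is thus a candidate explanation that the test cannot tell from such effects. The beta-actin controls had their widest gaps on CDP 1 and CMP 1. The Gapdh gap was wider on CDP 3 (6.60) than on CDP 1 (4.64) and CMP 1 (4.71), and narrower on CDP 2 and CMP 2. A difference that moves whole genes, such as another state of the replicate 1 cells, predicts that the probe sets of a gene shift together. That correlation was 0.34 (0.31 to 0.38), between the bounds set beforehand for and against, so it stays open beside the loss, and no biological difference between replicates is named by the labels.

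More probe sets were called higher (217) than lower (70) in CDP, which is 75.6% (95% exact binomial interval 70.2 to 80.5). At 1 probe set per gene 141 genes were higher and 40 lower. This interval and those below treat probe sets as independent, which they are not, so the shares are less sure than they read. If the array split, with 1 of 3 CDP and 1 of 2 CMP arrays low in 5′ signal, were the source, a block for it should bring the share to 60% or less. It stayed at 71.2% (68.8 to 73.5) of 1438 calls. If scaling were, quantile normalization or centring should do so, and the lower of their shares was 70.0% (63.9 to 75.5) of 253 calls. Among probe sets with an unadjusted p under 0.05 in limma, 1830 were higher and 810 lower in the main fit. Quantile normalization brought these to 1459 and 1047, and centring to 1463 and 1025. The called shares argue against the split as the whole source, as far as the interval holds. For scaling the called shares stayed above 60% too, but the counts at an unadjusted p under 0.05 in limma drew closer together. Scaling therefore stays open as a source. The filter needs 2 arrays at log2 5, which 3 CDP arrays can meet more easily than 2 CMP arrays. With a filter on the mean of either group the share was 75.7% (70.4 to 80.5) of 296 calls, but without a filter it was 52.7% (38.8 to 66.3) of 55 calls, so the filter stays open as a source of the excess. The 10 ways to split 5 arrays into 3 and 2 are too few for a share under 0.05: the real split gave 287 calls, the only 1 with as many, and the highest of the others gave 0. The difference between the cell types stays open as an explanation, untested by other means.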

How the results depend on the processing

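The settings on array quality, the centring, the filter on group means and the lists without gate genes were chosen only after the data were seen. All 56 named genes that were called kept their sign under each setting that tested them, 17 to 22 settings per gene. The 16 called lists kept the sign of their median under all 25 settings, except that the mast cell list had a median of 0 without a filter. The medians of the neutrophil and the megakaryocyte list came as near to 0 as -0.0012 and -0.026. Of 11 named genes not called, 5 changed sign under some setting, as their differences lay within their errors. Quantile and median scaling, the filter at log2 4, trended and robust variance, array weights, centring and a filter on the mean of either group left all 4 counts within 1.5 times. The filter at log2 7 left 45 probe sets lower in CDP, as fewer were tested. Without a filter 55 probe sets were called, 29 higher and 26 lower, among 45037 tested, and the cause was not tested. With camera's estimated correlation 0 lists were called, where fry called 13 and lost 4 of the main 16. Leaving out 1 array left 0 to 44 calls, 0 to 42 higher and 0 to 2 lower, with 13 to 17 lists. The highest count was without CDP 1, and where 1 CMP array remained it was assumed to vary like CDP. Fewer arrays leave fewer degrees of freedom. All main calls still tested kept their sign, which could not change, since the groups did not overlap on any of them. Without CDP 1, CDP 2 or CDP 3 their unadjusted p in limma also stayed under 0.05, though they had been selected on the same arrays. With the 2 arrays low in 5′ signal left out limma called 0, with 0 higher and 0 lower and 4683 at an unadjusted p under 0.05. The block for them gave 1438 calls (1024 higher, 414 lower). The beta-actin covariate gave 1608 (1161 higher, 447 lower), and the Gapdh covariate 0 (0 higher, 0 lower, 1517 at an unadjusted p under 0.05). These 2 covariates rank the arrays differently, and the cause of their opposite effects was not tested. With the replicate number as a block 608 probe sets were called (432 higher, 176 lower), among them all 287, and 17 lists. As replicate 3 occurs in CDP alone, CDP 3 adds nothing to that difference, which rests on replicates 1 and 2. The 2 CMP arrays deviate from their mean as mirror images, and both CDP 2 (0.58) and CDP 3 (0.33) went with CMP 2, so correlations of deviations cannot show whether equal numbers pair arrays. Signal over background limits the bounds: 112 of the 287 calls had all CMP arrays below log2 5 and 32 all CDP arrays.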

Other observations

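The test for mature dendritic cells was chosen only after the lymphocyte receptor pattern and some class II values were seen. Transcripts of mature marrow cells appeared on CDP 2 alone, noticed only when the values of genes left out by the filter were read. There 24 probe sets lay at least log2 5 above every other array, and 0 did so on each of the other 4 arrays. Among them were neutrophil genes, with S100a8 at 12.52, Ngp at 11.78, Chil3 at 11.36, Camp at 11.25, S100a9 at 10.76, Ltf at 10.61 and Lcn2 at 10.25, the erythroid genes Slc4a1 (9.89) and Alas2 (8.80), the immunoglobulin gene Igha (9.21) and Xist (7.75). Y-linked genes were detected on that array too. A candidate explanation is RNA or cells of mature marrow, in part from a female, in that sample, which no test was run on. The lineage-negative gate and the repeated sort should remove such cells, so the explanation needs them, or their RNA, to have come in despite both or later. Without CDP 2 all 285 called probe sets that could still be tested kept their sign. It could not have changed, since the groups did not overlap on any call. Their unadjusted p in limma stayed under 0.05, but they had been selected on the same arrays. In limma 0 passed the adjusted threshold, with 1535 at an unadjusted p under 0.05, and 17 of 21 lists were called.

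Granule genes, chosen after their values were seen, stayed bright in CDP. Mpo, Ctsg and Prtn3 were at 14.36, 13.48 and 12.95 (log2 means), with differences of -0.58 ± 0.32 (SE), -0.91 ± 0.31 and -0.36 ± 0.32 that did not pass, and Elane reached log2 5 only on CMP 2 (7.38).

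The lymphocyte receptor genes Klrd1 (at least 9.34-fold), Klrb1f (3.97 ± 0.39, not passing on another probe set) and Il7r (at least 2.27-fold) were higher in CDP. Klrb1f was picked after its value was seen. If NK or T cells had come with the sort, their abundant transcripts should too, but of 10 such genes 0 reached log2 5 on 2 CDP arrays and exceeded CMP by over 2 SE: Gzma, Cd3e and Cd3g lay at the lowest value on all arrays, and Nkg7 was higher in CMP. Of 10 B lineage genes 2 did (Cd79b and Vpreb1, both also among the lymphoid priming genes). Blnk was at 4.95 on average in CDP and at the lowest value in CMP, reaching log2 5 on CDP 2 alone, and Ebf1 (4.09), Ms4a1 (4.06) and Pou2af1 (4.02) had their highest values on CDP 2. Cd79a lay at the lowest value throughout. Outside these 10, Cd22 (3.71 ± 0.64) and Ighm (1.30 ± 0.34) of the lymphoid priming list met the same conditions. In that list 3 of 12 differences were negative. Of 10 genes of mature dendritic cells 1 did (H2-Aa), with Cd74 at 3.63 in CDP. Such cells are thus unlikely to be the source on all 3 CDP arrays, though traces on CDP 2 are not excluded. For the B lineage this is less sure, as its count of 2 lay at the limit set beforehand. Expression of these receptors by CDP themselves is a hypothesis that was not tested further.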
